A study of Homo sapiens with 6 samples.

How the data were processed

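The series measured RNA in H1299 cells, a human lung cancer line, on 1-colour (Cy3) Agilent arrays that carry probes for long non-coding RNA and mRNA. There were 3 arrays of cells given 10 µM daidzein for 24 h and 3 arrays of control cells given the solvent dimethyl sulfoxide for the same time. Samples were grouped and numbered from the labels, which do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

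The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers, whereas the submitters' processing notes give version 10.7. The processed intensity is background-corrected within an array and not normalized between arrays, and its column and the 0 or 1 flags were used as deposited, per the file headers. The deposited value table holds log2 values. Set against the scanner files, each of its columns equalled the mean log2 processed intensity of a probe's unflagged spots minus 1 constant per array (r = 1.0), with its 75th percentile at 0 and no centring of probes. Its column medians were -2.47, -2.55 and -2.47 for daidzein replicates 1 to 3, and -2.42, -2.45 and -2.40 for control replicates 1 to 3.

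Each array had 175906 non-control spots for 75149 probes. Spots flagged as non-uniform or population outliers were left out (1686 to 2181 per array) and the log2 values of a probe's remaining spots were averaged. No spot was saturated. Each array's 75th percentile of log2 processed intensity over non-control probes was subtracted. A probe counted as well above background on an array when the scanner software flagged over 0.5 of its spots so. Tests covered the 48797 probes that were well above background on all arrays of at least 1 group and had a value on all 6 arrays; another 284 passed the first condition and had an array on which all spots were flagged as outliers. The small number of arrays limits the precision.

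Differences were tested per probe with limma (version 3.58.1, R 4.3.3), lmFit and eBayes with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. RNA classes were tested with camera at its preset correlation of 0.01, over the 15 classes or ID series with at least 5 tested probes, and again with an estimated correlation and with fry. Single values of control probes were compared with a two-sided exact permutation test, whose smallest p for 3 arrays against 3 is 0.1. Data were simulated from the means and limma's moderated spreads of the 48797 probes for daidzein against control. The fit recovered 97 of 100 probes given a 2-fold change and 99 of 100 given a 3-fold change, with 15 false calls. It made 0 calls when nothing was changed. The simulated noise was independent between probes and arrays, with no effect of slide or position. These rates check the fit and do not give its power on the real arrays.

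The files do not pair probe IDs with gene names. The planned split into coding and non-coding genes, the gene lists, the choice among probes of a gene and the correlation of antisense partners all need names and were not run, and all counts are of probes. In their place, RNA classes were read from the probe names that give one; this was decided after seeing the data. The abbreviations imsncRNA and RNS are kept as the files give them. The rule for named features, fixed before the data were examined, took the strongest changes past the threshold with non-overlapping groups, and filled empty places by the lowest unadjusted p among changes of at least 1.5-fold with non-overlapping groups and the same sign in all 3 same-numbered pairs. Here it was applied to 1 probe and 1 named RNA in each direction, since probe IDs without names say little. Where a probe was not well above background on any array of a group, its own value there was set against the lowest signal well above background on that array. The fold was taken from the higher of them. It is an approximate lower bound where that lowest signal was the higher on some array, and otherwise the measured fold. Probes not well above background could read above that lowest signal, so it is no strict limit.

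Same-numbered arrays shared a slide and a scan, 1 of each group on each of 3 slides, so values within slides and from a fit with the slide (the replicate number) as a block are given beside the results. On every slide the daidzein array was at position 3 and the control array at position 4. Same-numbered arrays' deviations from their group means correlated at -0.03, -0.09 and 0.19. The alternatives were normexp with an offset of 50 on the median spot and background signals (the files hold no mean signal) with quantile normalization, quantile normalization alone, median centring, the percentile over detected probes, no filter on dim probes, probes detected on all 6 arrays, the deposited value table, slide as a fixed or random block, each array left out, trended and robust variance, other thresholds and a plain test without moderation. Cyclic loess, array quality weights, scaling on the 10 E1A spike-in probes and adjustment within ID series were added after seeing the data.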

Results

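H1299 is a human lung cancer cell line that lacks p53, and daidzein is a soy isoflavone that can bind estrogen receptors. The series asked which long non-coding RNAs and mRNAs differ between H1299 cells given 10 µM daidzein for 24 h and control cells given the solvent, with 3 arrays in each group. Of 75149 probes per array, 67.7%, 64.9% and 70.3% were well above background on daidzein arrays 1 to 3, and 67.9%, 63.9% and 68.5% on control arrays 1 to 3. The 75th percentile of processed signal was 461, 417 and 418 units on the daidzein arrays and 535, 476 and 483 on the control arrays, and all values below are log2 signals relative to it. Correlations between arrays across probes were 0.989 to 0.994 within groups and 0.986 to 0.992 between groups.

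Transfer RNAs are the adaptors that bring amino acids to the ribosome. Of 56 tested tRNA probes, 9 fell with daidzein and 0 rose when p was adjusted over the class alone, and none passed over all probes tested. With trended and robust variance 5 tRNA probes were higher and 11 lower over the class alone. The 9 falls ran from -0.49 to -1.34 on the log2 scale. The strongest was -1.34 ± 0.19 (SE, 3 arrays per group), with an adjusted p of 0.0025 over the class alone by limma. In all 9 the 3 daidzein values lay below the 3 control values, so the sign was the same on the 3 slides. The median of the 9 was -0.47 on slide 1, -0.66 on slide 2 and -1.07 on slide 3. All 9 also passed with the slide as a block. Another 6 tRNA probes had higher values at an unadjusted p under 0.05, with log2 differences of 0.23 to 0.56. Ranked by mean signal among all tested probes, 6 of the 9 falls lay in the dimmer 40%, 3 in the brighter 60% and 0 in the brightest 20%, which held all 6 higher ones. Across all probes the median log2 change ran the same way, from -0.06 in the dimmest 20% to 0.10 in the brightest 20%. The class as a whole had a mean of -0.14 and a median of 0.01, and camera did not call it (adjusted p = 0.13). Without daidzein replicate 2, daidzein replicate 3, control replicate 1 or control replicate 3, 5 of the 9 passed in each case.

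Small nuclear RNAs, a class that includes those of the spliceosome, had a lower mean than the other probes, and its call rested on camera's preset correlation. Their mean log2 change was -0.14 over 75 probes against -0.01 over all other probes. The probe names do not say which small nuclear RNA a probe reads. Camera gave an adjusted p of 0.0031, and the call was lost with an estimated correlation (adjusted p = 0.23). Fry gave an adjusted p of 0.17. In other splits of the 6 arrays into 3 and 3, camera at its preset called up to 8 classes, against 6 in the real split. With normexp the difference from the other probes was -0.08 in place of -0.14. The difference from the other probes was -0.09 on slide 1, -0.08 on slide 2 and -0.25 on slide 3, and the adjusted p with the slide as a block was 0.0062. Adjusted over the class alone, 3 snRNA probes fell, by -0.49 to -0.83, and 0 rose; with the slide as a block 0 passed, no filter on dim probes gave 0, and leaving out single arrays gave 0 to 5, with 0 without daidzein replicate 1 or control replicate 3. Probes of small nucleolar and Cajal body RNAs, which guide chemical modification of other RNAs, showed no shift: the mean log2 change over 241 probes was 0.01 and camera gave an adjusted p of 1.0. The probe for snoRNA_scaRNA_30_147 rose, with a limma adjusted p of 0.017 over the class alone, and did not pass over all probes (adjusted p = 0.059). Its log2 signal was -1.04 ± 0.11 with daidzein and -1.84 ± 0.12 in control (SD over 3 arrays), a 1.74-fold difference that was 0.81, 0.79 and 0.81 on the 3 slides in log2. Over the class alone the adjusted p was 0.0496 with the slide as a block, 0.076 without daidzein replicate 1, 0.053 without control replicate 2, 0.12 without control replicate 3 and 0.094 with no filter on dim probes. Of 10 ribosomal RNA probes, 1 fell, by 0.45 on the log2 scale, over the class alone; with the slide as a block 0 passed, with trended and robust variance 2 were higher and 2 lower, and no rRNA probe passed as lower without daidzein replicate 1 or 3 or control replicate 1 or 3. Camera called neither the rRNA class nor the 996 probes named RNS (adjusted p = 0.77 for both).

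The class that the files name imsncRNA had a slightly lower mean log2 change, -0.08 over 695 probes, with a camera adjusted p of 0.019. That call was again lost with an estimated correlation (adjusted p = 0.43), and fry gave an adjusted p of 0.22. The difference of the class from the other probes was -0.09, 0.01 and -0.13 on slides 1 to 3. The camera adjusted p with the slide as a block was 0.024. Over the class alone 10 probes fell, with log2 changes of -0.55 to -1.28, and 0 rose. With the slide as a block 5 passed, and with trended and robust variance 4 did. Leaving out single arrays gave 0 (control replicate 3) to 31 (daidzein replicate 2) lower probes, and normexp and the setting with no filter on dim probes gave 0. Shifts of similar size were found in series of probes that have an ID and no RNA class. Relative to all other probes, those with IDs starting p changed by -0.08 and those ending in v4 by -0.07, while the A_23 and A_24 series changed by 0.12 and 0.08. Camera called these 4 series (adjusted p = 5.0e-06 for A_23 and 0.0031 for the others), with signs that were the same on the 3 slides. With the slide as a block the adjusted p was 5.9e-06 for A_23 and 0.0044 for the others, and with an estimated correlation it was 0.22 for all 4. Both probes of imsncRNA273 were among the lowest in p. One changed by -0.997 ± 0.11 (SE) and the other by -0.88 ± 0.11, with limma adjusted p of 0.0096 and 0.011 over the class alone and 0.059 over all probes for both. The first was well above background on 2 of the 3 daidzein arrays. Within slides 1 to 3 the first differed by -0.77, -1.06 and -1.17 and the second by -0.87, -1.04 and -0.73. With normexp the log2 changes were -0.26 for the first and -0.36 for the second.

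**Figure D1:**
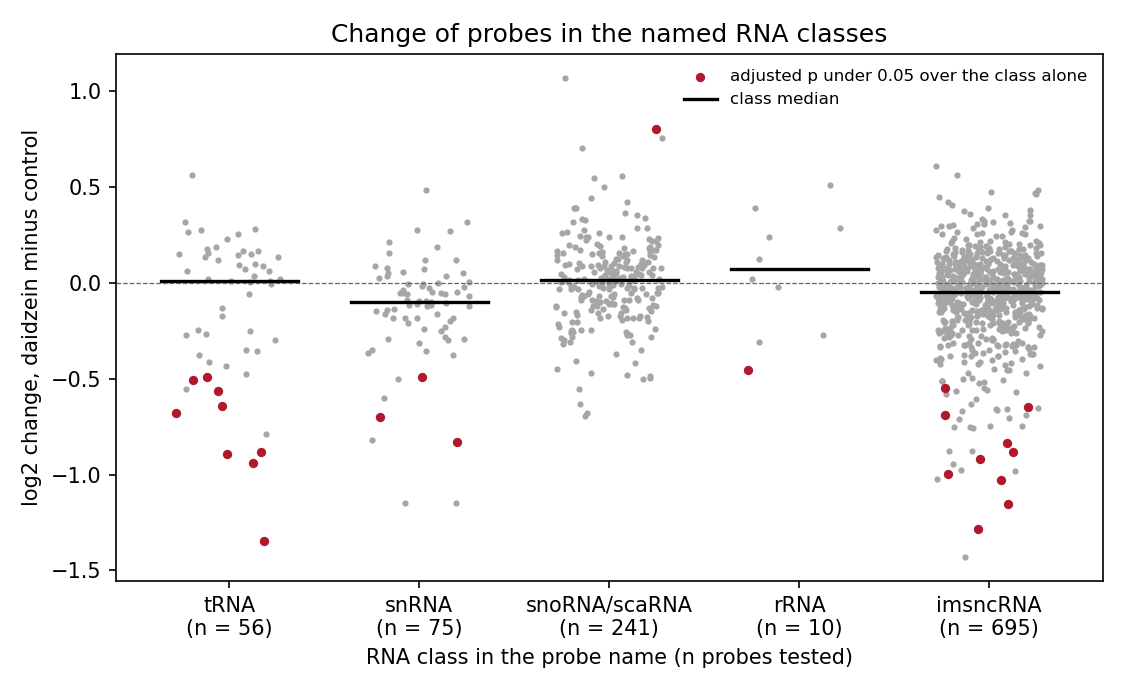
Log2 change (daidzein minus control, vertical axis) of each tested probe in 5 RNA classes (horizontal axis); each point is a probe, red points have an adjusted p under 0.05 over their class alone, and black bars are class medians. The 9 red tRNA points lie between -0.49 and -1.34, while the tRNA median is 0.01.

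Over all probes, 1 passed the adjusted threshold and it fell: A_23_P108743, with an adjusted p of 0.036 by limma. It was well above background on all 3 control arrays and on no daidzein array. With the lowest signal well above background put in where its own was lower, its signal was 2.41-fold lower with daidzein. This is an approximate bound in the main setting, where the log2 change was -1.66. With normexp the log2 change was -0.38 (adjusted p = 0.070 by limma). The daidzein array read lower on each of the 3 slides, and with the slide as a block the adjusted p was 0.18. The strongest rise, p10110, did not pass (adjusted p = 0.059). It was well above background on all 3 daidzein arrays and no control array. Its measured difference was 2.91-fold, a log2 change of 1.54 ± 0.15 (SE). With normexp and its offset the log2 change was 0.53 (adjusted p = 0.036 by limma). By the rule that picked it, it read higher on the daidzein array of each slide. Its adjusted p with the slide as a block was 0.18. The files give no gene for either probe.

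Probes for GAPDH and PGK1, both enzymes of glycolysis, are spotted on the array as controls and read about the same shift at both ends of each transcript. The GAPDH probe near the 3' end gave 6.59 ± 0.05 with daidzein and 6.36 ± 0.02 in control (SD), and the one near the 5' end 6.95 ± 0.04 and 6.71 ± 0.01. For PGK1 the values were 4.41 ± 0.18 and 4.14 ± 0.10 near the 3' end, and 1.79 ± 0.18 and 1.57 ± 0.02 near the 5' end. The PGK1 differences on slides 1 to 3 were 0.08, 0.59 and 0.14 near the 3' end and 0.08, 0.40 and 0.17 near the 5' end, and without daidzein replicate 2 their means went from 0.27 to 0.17 and from 0.22 to 0.12. Relative to the 75th percentile all 4 probes were higher on the daidzein array of each slide. Each had an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow, and an adjusted p of 0.17 over the 10 control measures compared. The unscaled log2 signal of the negative control probe had the same p values in the other direction, at 2.06 ± 0.30 with daidzein and 2.47 ± 0.23 in control (SD), and differed by -0.25, -0.47 and -0.53 on slides 1 to 3; the 75th percentile itself differed by -0.21, -0.19 and -0.21. The scaled differences were 0.23 and 0.24 for GAPDH and 0.27 and 0.22 for PGK1, in the order 3' then 5'. The mean difference of the percentile was -0.20, so most of each came from the scaling. On slide 1 none of the 4 was larger in size than the percentile's -0.21. Scaled on the E1A spike-in probes instead, the log2 differences were 0.09 and 0.11 for GAPDH and 0.13 and 0.08 for PGK1, in the same order. The difference between the 3' and 5' probes, a sign of RNA integrity, was -0.36 ± 0.02 with daidzein and -0.34 ± 0.03 in control for GAPDH (exact permutation p = 0.6), and 2.62 ± 0.02 and 2.57 ± 0.11 for PGK1 (exact permutation p = 0.9).

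**Figure D2:**
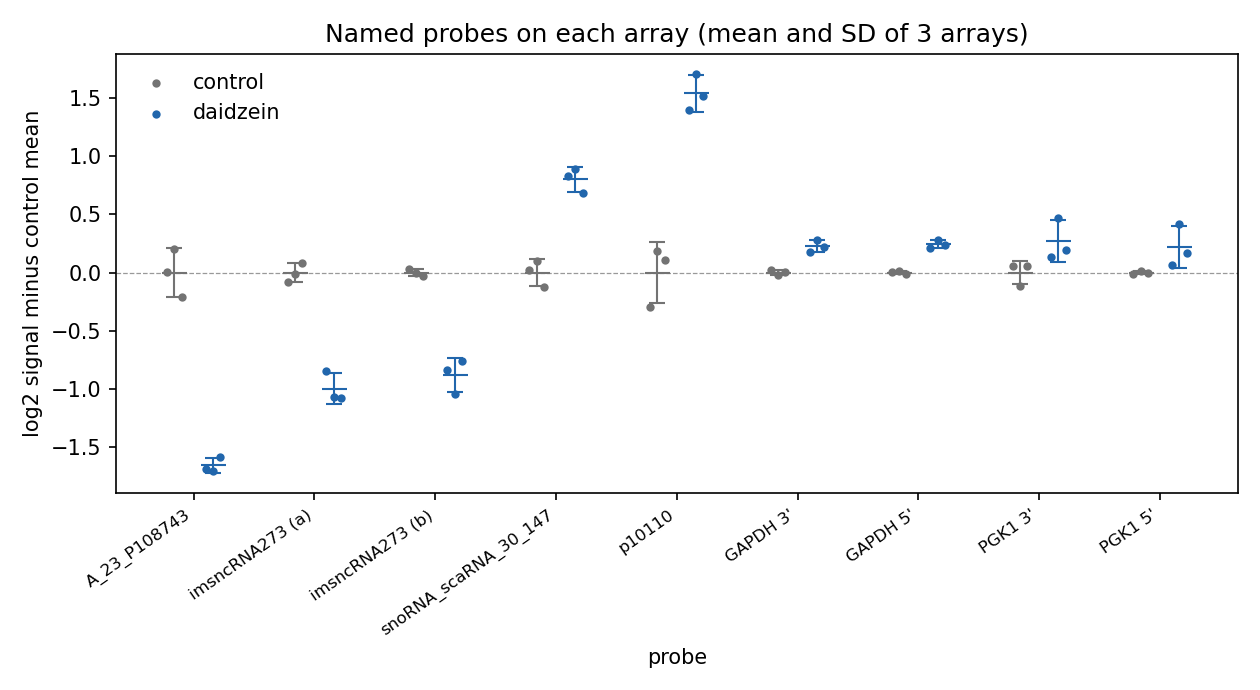
Log2 signal of each array minus the control mean (vertical axis) for the named probes, the 2 probes of imsncRNA273 (a and b) and the GAPDH and PGK1 control probes (horizontal axis); points are single arrays, bars are the mean and SD of 3. Daidzein arrays lie below every control array for A_23_P108743 and imsncRNA273, and above for the others shown. Groups that do not overlap were a condition for picking the named probes, though not for imsncRNA273 (b) or the control probes. A_23_P108743 was not well above background on the daidzein arrays, nor p10110 on the control arrays, so the sizes of their plotted differences are uncertain.

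Across all 48797 tested probes, 9229 (18.9%, against 5% by chance) had an unadjusted p under 0.05, 4832 higher and 4397 lower with daidzein. Without control replicate 3 these counts were 2853 and 2997. The groups did not overlap for 12424 probes (25.5%, against 10% by chance). Changes of at least 2-fold at that p were nearly all downward, with 143 probes lower and 7 higher. Of these, 121 of the falls and 6 of the rises were among the dimmer 40% of tested probes by mean signal. Normexp with quantile normalization gave 5 lower and 0 higher and scaling on the E1A spike-in probes 312 and 4. Without daidzein replicate 1 the counts were 241 and 10, without daidzein replicate 2 they were 227 and 19, without control replicate 1 they were 254 and 21, and without control replicate 3 they were 102 and 12. At 1.5-fold, 1197 were lower and 253 higher. With the slide as a block the 2-fold counts were 140 and 7, and 0 probes passed the adjusted threshold (lowest adjusted p = 0.18), with 4768 higher and 4378 lower at an unadjusted p under 0.05. Scaling on the percentile over detected probes gave 3199 higher and 5903 lower at an unadjusted p under 0.05, and scaling on the E1A spike-in probes, which moved the median change of all probes from 0.01 to -0.12, gave 940 and 7514. At the adjusted threshold normexp gave 152 higher and 307 lower, and trended and robust variance 340 and 428. Without daidzein replicate 2, 20 probes were higher and 147 lower at that threshold; without any other single array 0 passed.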

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

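The comparisons in this part were chosen after the results were seen. Of 53 control features of the array outside the main measurement, 5 were higher on all 3 daidzein arrays than on all 3 control arrays, where chance gives 2.65, and 4 of the 5 were well above background. The bright corner spots, which mark the corners of the array, were higher by 0.46 in log2 relative to the 75th percentile, and by 0.26 before scaling (0.10, 0.26 and 0.41 on slides 1 to 3). The mouse GAPDH 3' probe was higher by 0.34, the mouse PGK1 5' probe by 0.17 and the rat PGK1 5' probe by 0.16. Before scaling these 3 differed by 0.13, -0.04 and -0.04, and each had both signs over the 3 slides.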

How the results depend on the processing

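Cyclic loess, array quality weights, E1A scaling, adjustment within ID series and the tests by class and by class alone were chosen after seeing the data. The planned mean over probes of a gene, adjustment within coding or non-coding genes, gene lists and antisense correlation were not run, since they need gene names. Signal over background limits dim probes. The causes of these differences between settings were not tested.

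At the adjusted threshold, 0 probes were higher and 1 lower. Normexp with quantile normalization gave 152 higher and 307 lower, the percentile over detected probes 6 and 93, slide as a random block 33 and 145, trended and robust variance 340 and 428, array quality weights 108 and 299, and E1A scaling 2 and 177. Quantile normalization, no filter on dim probes, probes detected on all 6 arrays and cyclic loess gave 0 and 0. Leaving out single arrays gave 0 to 20 higher and 0 to 147 lower. The plain test without moderation gave 1 higher and 0 lower after Benjamini-Hochberg, and 6 and 105 at unadjusted p with a 2-fold change, where limma gave 7 and 143. Adjustment within 3 broad ID series (IDs starting A, IDs starting p, and RNA names) gave 9 and 80. At an adjusted p under 0.1 by limma, the main setting gave 396 higher and 697 lower. The slide as a fixed block and no filter on dim probes each gave 0 and 0 there. The most were 1781 higher with trended and robust variance and 1635 lower with array quality weights.

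At 2-fold and unadjusted p (7 higher, 143 lower), normexp gave 0 and 5, quantile normalization 15 and 104, no filter 39 and 398, probes detected on all 6 arrays 2 and 67, cyclic loess 11 and 117, array quality weights 13 and 164 and E1A scaling 4 and 312. Single arrays left out gave 9 to 21 higher and 102 to 254 lower. Falls outnumbered rises under every alternative named here.

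Over the class alone, 1 named-class probe was higher and 23 lower. Normexp gave 4 and 14, no filter 0 and 6, probes detected on all 6 arrays 2 and 18, trended and robust variance 10 and 22 (5 and 11 of them tRNA), array quality weights 3 and 42, and E1A scaling 2 and 48. Single arrays left out gave 0 to 4 higher and 5 to 45 lower, the most without daidzein replicate 2 and the fewest without control replicate 3. The 9 tRNA probes were lower in every setting that tested them, and at least 5 of them passed in each.

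The replicate block gave 0 probes higher and 0 lower at the adjusted threshold and 14 named-class probes lower over the class alone; it changed the call of none of the 6 named classes. Same-numbered arrays share a slide and a scan, and nothing shows that the samples themselves were paired: 2 of the 6 arrays deviated most like the other array of the same number.

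The mean change of snRNA probes less that of the rest was -0.137; it lost its call with an estimated correlation (adjusted p = 0.23) at the same value, and kept it under the other camera settings, with -0.0791 for normexp and -0.108 to -0.157 over left-out arrays. For imsncRNA, at -0.0727, the call was lost with an estimated correlation, without the filter (-0.0526), and without daidzein replicate 3 or control replicate 1. Left-out arrays gave -0.0549 to -0.0983 and all alternatives -0.0416 (normexp) to -0.0983. For tRNA, at -0.135 with no call, normexp (-0.135), quantile normalization (-0.177) and cyclic loess (-0.191) gave a call, as did leaving out daidzein replicate 1. Left-out arrays gave -0.107 to -0.177 and all alternatives -0.107 to -0.191. The p series lost its call with normexp (adjusted p = 0.060), quantile normalization (0.079) and cyclic loess (0.075), in a range of 0.0013 to 0.22, and the series ending in v4 lost it without the filter (0.082). Fry, which tests a class's own change and not its difference from other probes, gave an adjusted p of 0.17 for snRNA, 0.22 for imsncRNA and 0.21 for tRNA. A_23_P108743 passed in 8 of 18 alternatives (adjusted p 0.018 to 0.21), p10110 in 7 of 18 (0.027 to 0.24) and snoRNA_scaRNA_30_147 in 5 of 19 (0.030 to 0.24), and the direction did not turn.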

Other observations

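The fits to other splits of the arrays, the explanations weighed and the test of probe pairs were chosen after the results were seen. A fit to each of the 10 splits of the 6 arrays into 3 and 3 gave 24 named-class probes past the adjustment over their class for the real split and at most 1 for any other. The real split gave 1 probe past the adjusted threshold against at most 0, 150 against at most 45 at 2-fold and unadjusted p, and 9229 against at most 3231 at unadjusted p; in each of these 4 counts 1 split, the real one, reached the count. With 10 splits no share under 0.05 can be had. All splits used the probes chosen for signal over background in the real groups, which can favour the real split. With probes detected on all 6 arrays the real split gave 67 lower and 2 higher at 2-fold and unadjusted p. The other splits were not fitted on those probes, so these counts cannot be set against theirs. The real split is also the split by position on the slide. For camera the real split called 6 classes, 3 of the 10 splits called as many, and the highest other called 8. With an estimated correlation the real split called 0 classes.

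The 9 tRNA probes that fell were set against an intensity-dependent difference between arrays and against poorer recovery of short RNA from the daidzein samples. After cyclic loess 9 of the 9 still passed over the class alone, at -0.49 to -1.28, which argues against the first as the whole cause. Poorer recovery of all short RNA would lower snoRNA and scaRNA probes too. Their median change was 0.0148 (SD 0.24 over probes), far above the smallest tRNA fall of -0.49. With spike-in scaling the values were -0.12 and -0.63. A loss limited to RNA as short as tRNA was not tested by this. The median change of all tested tRNA probes was 0.01. Of the 9, 6 lay in the dimmer 40% of probes, where a difference in background was not excluded. A treatment effect on some tRNAs, array position and probes that read the same tRNA more than once stay open.

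Falls made up 95.3% of the 2-fold changes at unadjusted p. After cyclic loess falls were still 91.4%, which argues against an intensity trend as the whole cause. When probes were ranked by mean signal, the brighter 60% held 22 falls and 1 rise. The two-sided exact binomial p was 5.72e-06, over probes, which are not independent. The excess of falls was thus not limited to the dimmer 40%. The brighter 60% was cut into 3 parts of about equal size. From dim to bright they held 17, 3 and 2 falls, and the 1 rise lay in the dimmest. A difference in background was therefore not excluded there. Most of the pattern, 121 falls and 6 rises, lay in the dimmer 40%, where a difference in background stays open too. Normexp left 116 of the 121 lower at unadjusted p, but 5 falls of 2-fold over all tested probes, the brighter 60% included. Before scaling, the negative control read lower by 0.42 in log2 on the daidzein arrays, while the 75th percentile itself differed by -0.20. Position on the slide cannot be told apart from the group, since the daidzein array was at the same position on 3 of 3 slides. An effect of daidzein was not tested apart from it.

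One hypothesis was that changes of imsncRNA probes belong to the RNA and not to the single probe. Over the 34 imsncRNAs with 2 tested probes, the log2 changes of the pair correlated with Pearson's r = 0.75 (permutation p = 1e-05, the smallest the resamples can give) and Spearman's rho = 0.49 (permutation p = 0.0038), and r was 0.64 without the 2 RNAs farthest from the median. The correlation is across RNAs, which are not independent replicates, and 25 of the 34 pairs had the same sign. The correlation over pairs is what the hypothesis predicts, and overlap of the probes' sequences, which was not tested, could give it too. RNAs with more than 2 tested probes were not in the test. Of these, imsncRNA249, imsncRNA843, imsncRNA846 and imsncRNA848 had changes of both signs among their probes, and imsncRNA743 and imsncRNA841 only falls.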
